A study of Mus musculus with 200 samples.

How the data were processed

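Polyadenylated RNA of 200 mouse libraries was amplified from about 10 to 100 cells each by Smart-seq2, per the labels' protocols. The deposited tables hold TPM, a measure of transcript abundance scaled to a fixed total per library. Per the submitters' processing notes, HISAT2 2.2.1, StringTie 2.2.1 and Cufflinks were used with the mm10 genome; the notes do not state the role of each tool. Columns summed to between 984852 and 993453 TPM. The 7 tables were treated as normalized separately and no gene or list test compared libraries of different tables. Only weighing PrE cells with GSK-J4 and checking EB row order set TPM of one table against another. Without read counts, the depth of each library and the counting error of each value are unknown. Adjusted p-values measure only the spread between libraries of a group, and where these were amplified from shared embryos that spread may be technical. The GSK-J4 dose of 50 µM is given for the E5.0 design only.

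The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except for alternatives and tests said to have been added later. TPM of repeated symbols were summed. Genes at 1 TPM or more in at least as many libraries as the smaller group holds were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a linear model and moderated variances that follow the mean expression (eBayes with trend). Benjamini-Hochberg adjustment ran within each comparison, with a threshold of 0.05. The GSK-J4, Zbtb17 E4.5 and dTAG tables were each fitted alone. Epi and PrE of the Suz12 Eed table shared a fit, as did the days of the EB table and the batches of the screen, where each knockout was compared with the controls of its own batch. The difference between Epi and PrE, and between days, was tested by interaction terms. Tables were read with the R package data.table, version 1.17.8, and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

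There were 20 gene lists: naive pluripotency, core pluripotency, formative and primed pluripotency, developmental Polycomb targets, gastrulation and mesendoderm, Nodal pathway targets, primitive endoderm markers, and trophectoderm and extraembryonic ectoderm markers. Others were blood, stromal and fibroblast markers, p53 targets, ATF4 and amino acid stress, glycolysis and hypoxia, ribosome biogenesis, mitosis, autophagy and vesicle trafficking, germline, 2-cell stage, imprinted genes, Polycomb and H3K27 or H3K4 methylation machinery, and mitochondrially encoded genes. The last had 0 measured members. Lists with at least 5 measured members were tested with camera in limma, with a preset correlation of 0.01 and again with an estimated one. Adjustment ran over lists within a comparison, and over lists and knockouts together in the screen.

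Named genes were the targeted genes and, per comparison, the 8 largest rises and 8 largest falls among genes that passed, with groups that do not overlap and a higher mean of at least 5 TPM. Clone names, predicted genes and pseudogenes were left out, and where fewer than 5 passed, the 5 genes with the smallest p were taken. Added to these were up to 4 members per list that passed, or up to 2 where none did, 4 rises and 4 falls in each of the 8 screen knockouts with most calls, and 10 genes shared by Zbtb17 perturbations. Where a group was at 0 in every library no fold is given. Coordinates came from GENCODE vM21 on mm10, which matched 24183 of 25006 symbols.

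The EB table has no gene column. Its 25006 values per library were taken in the order shared by 3 other tables of the same length. Across genes, EB levels correlated with those of the other tables at 0.904 in this order, at most at 0.11 when shifted by 1 to 5 places, and at -0.0141 in alphabetical order. Of 50 windows of 500 genes, 50 correlated best without a shift, the lowest at 0.86. PrE control replicates 1 and 2 were nearly identical and were averaged to 1 library. The 3 Aurkb knockout libraries were also nearly identical and were averaged. The Aurkb knockout was then not tested, by choice, although the shared spread would have allowed it. The averaged PrE pair correlated at 0.994 and the Aurkb libraries at 0.997. These were picked by eye, as more alike than other libraries of their tables, and no threshold was set beforehand. EB pairs were about as alike, at 0.992 to 0.994 in all groups, and were kept as 2 libraries a group because none stood apart. Averaging them was not tried, and EB p-values rest on the spread within these pairs.

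Whether equal replicate numbers pair libraries was checked in 48 comparisons by correlating deviations from group means. Every one of 3 pairs was over 0.1 in the Suz12 Eed Epi comparison (0.16 to 0.37) and the Wt1 knockout (0.13 to 0.48) only. The labels do not say what a number marks. Alternatives were a 2-fold minimum, a pseudocount of 0.1, no filter, quantile normalization, library weights, the replicate number as a block, fits of only the compared groups or the same batch, and each library left out. The groups were also split in other ways, with 100 random assignments within EB days and 50 within screen batches.

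The fits were tested on simulated data with 200 changed genes. At 2-, 4- and 8-fold, 11.9%, 29.9% and 56.1% were recovered for GSK-J4 at E4.5 (10396 genes), 29.9%, 64.2% and 83.3% at E5.0 (10722 genes), and 47.8%, 92.5% and 95.5% for the double knockout in Epi (11117 genes). Recovery was 34.3%, 86.6% and 95.5% in PrE (10366 genes), 35.8%, 80.6% and 92.4% for the Zbtb17 knockout at E5.0 (10336 genes), and 37.3%, 70.1% and 87.9% for dTAG (10565 genes). It was 98.5%, 100% and 100% for EB day 3 (12923 genes). For the Zbtb17 knockout at E4.5 it was 0%, 0% and 15.2% (5947 genes), so most changes of these sizes would go undetected there. With no change and each group's own spread, 70 genes were called in PrE and 840 in the Zbtb17 knockout at E5.0.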

Results

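The series measured polyadenylated RNA by Smart-seq2, a full-length cDNA method for small numbers of cells, in 200 mouse libraries that fell into 70 groups and 7 tables. Embryo libraries were labelled epiblast (Epi), which forms the embryo proper, or primitive endoderm (PrE), which forms the yolk sac endoderm. The others came from embryoid bodies (EB), aggregates of differentiating embryonic stem cells. A screen table held 148 Epi libraries in 10 batches, with the controls of each batch and 40 knockouts made by C-CRISPR, in which several guide RNAs target 1 gene. GSK-J4, an inhibitor of the H3K27 demethylases Kdm6a and Kdm6b, had a table of 6 libraries at E4.5 and another of 6 at E5.0. The Suz12 Eed double knockout in Epi and PrE had 12 libraries. Zbtb17 was perturbed by knockout at E4.5 with 6 libraries, by a degron (dTAG, which removes a tagged protein) at E5.0 with 6, and by knockout in EB on days 0 to 3 with 16. Embryo groups held 3 libraries each, except the batch 7 controls and the Ascl2 knockout with 2, and EB groups held 2. A nearly identical pair of PrE control libraries was counted as 1, and so were the 3 of the Aurkb knockout, which was not tested. Without read counts the depth of each library is unknown. Libraries had 9465 to 9864 genes at 1 TPM or more in the GSK-J4 table at E4.5, 9945 to 10480 at E5.0, 9740 to 11279 in the Suz12 Eed table and 7236 to 11315 in the screen. The range was 3986 to 4952 in the Zbtb17 table at E4.5, 10236 to 10645 in the dTAG table and 5970 to 13512 in EB. Values are means in TPM ± SD over 3 libraries a group unless another n is given, perturbed group first, and log2 changes are on TPM + 1. List tests are given with a preset correlation, and where no second adjusted p follows, the call held with an estimated correlation.

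Transcripts of the targeted genes were lower in part of the perturbations. In the double knockout, the Polycomb repressive complex 2 subunit Eed (mm10 chromosome 7, 89954654 to 89980983) fell in Epi from 179 ± 23.3 to 45.2 ± 6.47 TPM (adjusted p = 3.92e-06). In PrE it fell from 166 ± 7.63 (n = 2) to 55.5 ± 7.12 TPM (adjusted p = 5.92e-05). Suz12, another subunit (chromosome 11, 79993106 to 80034123), fell in Epi from 24.7 ± 4.14 to 11.9 ± 5.48 TPM (adjusted p = 0.029), and in PrE from 29.4 ± 1.34 (n = 2) to 15.1 ± 2.26 TPM (adjusted p = 0.0417). Among 40 targeted genes of the screen, 39 were measured, 8 fell, 3 rose and 28 did not pass the test. Those that fell included Suz12 (25.5 ± 6.23 to 4.50 ± 0.863 TPM), Hdac1 (157 ± 34.1 to 32.8 ± 7.62), Fos (45.9 ± 16.6 to 10.5 ± 3.46) and Tfap2c (51.8 ± 7.86 to 16 ± 4.91). They also included Ezh2 (48.4 ± 11.3 to 15 ± 6.45), Elf5 (79.8 ± 5.20 to 38.6 ± 24.3), Bend3 in batch 8 (32.0 ± 13.2 to 10.3 ± 0.435) and Zfp57 (17.4 ± 8.36 to 7.85 ± 7.42). Within the batch alone Zfp57 did not pass (adjusted p = 0.323), while Hdac3, Hsf2, Mta2 and Rnf2 fell (at most 0.0213) and Zfp281 rose (0.000915).

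Myc, Cxxc1 and Bend3 in batch 7 rose in libraries labelled as their knockouts. Myc, a growth-promoting transcription factor, rose from 56.6 ± 11.7 to 145 ± 14.2 TPM (adjusted p = 2.69e-07). Cxxc1, a subunit of H3K4 methyltransferase complexes, rose from 1.73 ± 1.17 to 8.54 ± 3.46 TPM (adjusted p = 0.012, 0.106 within its batch). Bend3 rose from 4.87 ± 1.16 (n = 2) to 12.5 ± 8.57 TPM (adjusted p = 0.037, 0.767 within its batch). Zbtb17, a zinc finger factor also known as Miz1 (chromosome 4, 141444654 to 141467930), did not pass in the E5.0 knockout at 6.93 ± 7.09 TPM against 2.65 ± 2.06 (adjusted p = 0.488). Nor did it in the dTAG table at 6.21 ± 0.640 TPM against 3.11 ± 1.85 (adjusted p = 0.246). Its level was too low to test at E4.5 and in EB on day 0. In EB it fell on day 1 from 22.1 ± 1.85 to 10.0 ± 0.174 TPM (n = 2 and 2, adjusted p = 1.89e-06). It also fell on day 2, from 21.9 ± 1.20 to 13.4 ± 1.06 TPM, and on day 3, from 17.7 ± 0.472 to 13.5 ± 0.243 TPM. A degron acts on protein and C-CRISPR can leave a transcript behind, so a level that did not fall checks nothing by itself.

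**Figure D1:**
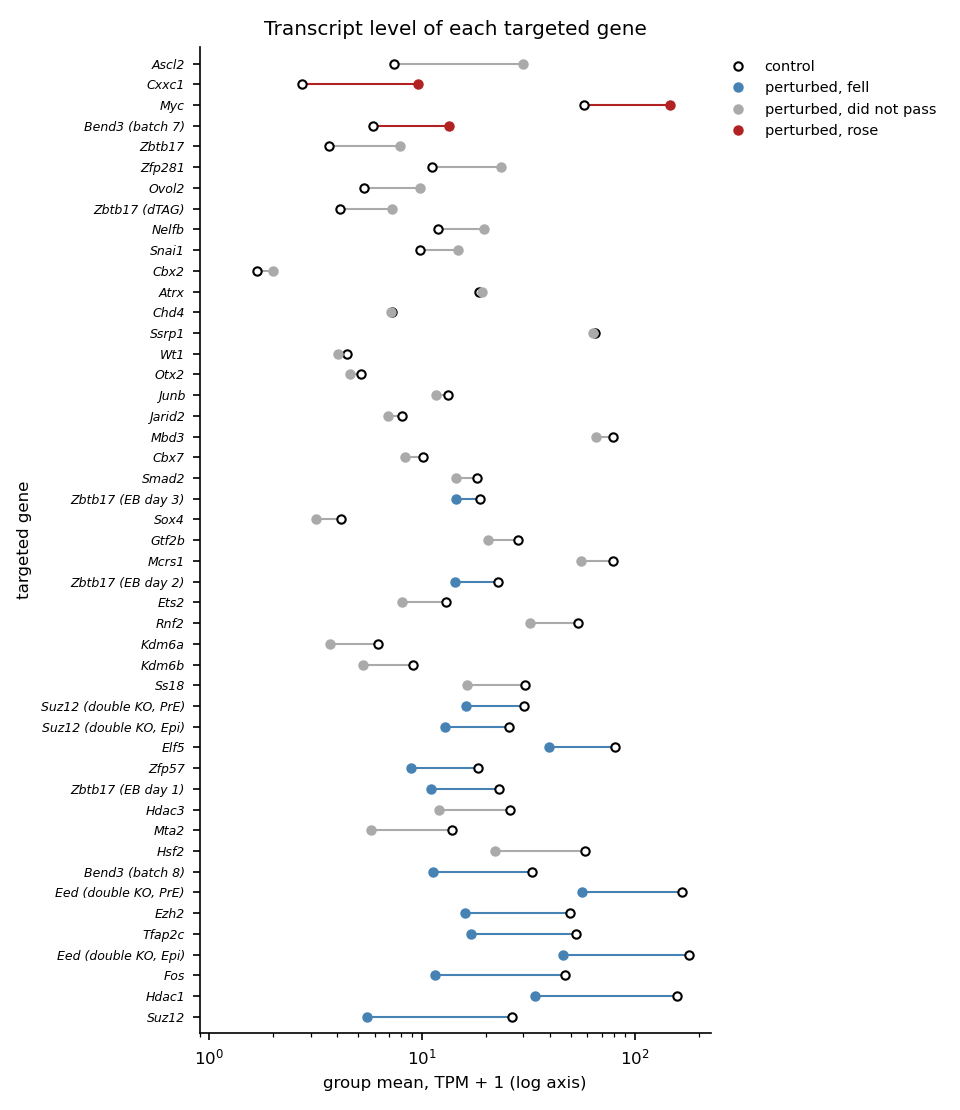
Each line joins the control mean (open circle) and the perturbed mean (filled circle) of a targeted gene in TPM + 1 on a log axis, coloured by whether the gene fell, rose or did not pass the test. In the screen 8 of the 39 measured targets fell and 3 rose.

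GSK-J4 at E4.5 tested what inhibiting the H3K27 demethylases does to the early epiblast. The largest falls included Ctsll3, a cathepsin L-like gene, at 0.965 ± 1.67 TPM against 321 ± 26.3 (log2 change -7.67, adjusted p = 5.59e-05). The trophectoderm factor Tfap2c was at 0.801 ± 0.896 TPM against 20.5 ± 2.26 (log2 change -3.68, adjusted p = 0.0409). Ptpn6, a tyrosine phosphatase, fell to 2.14 ± 2.33 against 35.6 ± 7.24, and Entpd1, an ectonucleotidase, to 2.29 ± 3.37 against 37.8 ± 11.7. Among the rises, the gut hormone Pyy was at 41.7 ± 13.6 TPM against 0.435 ± 0.753 (log2 change 4.97, adjusted p = 0.00775) and the heat shock protein Hspa1a at 27.2 ± 13.5 against 0.0219 ± 0.0192. The actin regulator Pfn2 rose to 30.1 ± 6.68 against 1.15 ± 1.61 and the chemokine receptor Ackr3 to 16.9 ± 2.69 against 0.194 ± 0.336. Tpsg1, a tryptase, was at 56.2 ± 20 TPM against a listed 0 (adjusted p = 0.00222). The remaining genes of the fixed rule were Xkr9, H2-Aa and Zfp972 among rises and Tagln3, S100a8, Agrp and Ldoc1 among falls.

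By gene list, 3 of 14 measured trophectoderm and extraembryonic ectoderm markers fell and 0 rose at E4.5 (median log2 change -0.52, adjusted p = 0.00349, but adjusted p = 0.117 with an estimated correlation). The members were the keratins Krt7, at 20.3 ± 12.2 against 127 ± 27.8, and Krt8, at 361 ± 42.7 against 587 ± 43, and the placental gene Plac1, at 68.8 ± 26.5 against 227 ± 37.5. Of 24 primitive endoderm markers 1 rose, the lipid carrier Apoe at 4560 ± 281 against 3570 ± 201 (median log2 change 0.3, adjusted p = 0.00687, but adjusted p = 0.117 with an estimated correlation). The glycolysis and hypoxia list had 3 of 19 members fall, the enzymes Eno1, Pkm and Aldoa (median log2 change -0.41, adjusted p = 0.00311, but adjusted p = 0.117 with an estimated correlation). Their log2 changes were -0.61, -0.6 and -0.47. The serine synthesis enzyme Psat1, at 543 ± 27.3 against 866 ± 32.4, was the 1 of 18 ATF4 and amino acid stress genes that fell (median log2 change -0.61, adjusted p = 1.53e-04, but adjusted p = 0.117 with an estimated correlation). Adjusted over the list alone, 5 fell. In the mitosis list 1 of 20 fell, the anaphase activator Cdc20 at 374 ± 27.4 against 693 ± 32 (median log2 change -0.32, adjusted p = 0.0169, but adjusted p = 0.152 with an estimated correlation). That list call was lost without control replicate 3 (adjusted p = 0.0668). Dppa3, a maternal factor of the naive state, rose to 366 ± 32.3 TPM against 81.7 ± 8.87 (log2 change 2.15, adjusted p = 2.05e-04). Dppa3 and Dppa5a, at 27200 ± 824 against 19300 ± 488, were the 2 of 15 naive pluripotency genes that passed (list adjusted p = 0.0596). Otx2 was at 4.29 ± 3.54 TPM against 26.5 ± 19.2 (log2 change -2.35, adjusted p = 0.229). The core, formative, Polycomb target, Nodal and p53 lists did not pass (adjusted p of 0.0596, 0.0688, 0.557, 0.13 and 0.173). Nor did the ribosome (0.0549; 0.0422 with the replicate number as a block), autophagy, germline, imprinted and machinery lists (0.13, 0.68, 0.173 and 0.994). In all, limma called 115 of 9982 genes, 61 higher and 54 lower. Leaving out a library moved this count by over 1.5 times in each case, to 60, 57 and 48 without control replicates 1, 2 and 3 and to 39, 50 and 58 without treated replicates 1, 2 and 3.

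At E5.0 the GSK-J4 libraries carried high levels of endoderm transcripts. The secreted inhibitor Spink1 rose to 473 ± 62.7 TPM against 0.888 ± 0.85 (log2 change 8.08, adjusted p = 9.1e-06) and the alcohol dehydrogenase Adh1 to 509.5 ± 91.9 against 1.23 ± 1.49. The adhesion protein Flrt3 rose to 315 ± 42.4 against 0.676 ± 0.541 and the glucose transporter Slc2a3 to 509.6 ± 70.1 against 3.42 ± 1.61. The serum proteins Apoa1, at 164 ± 28.1 against 0.486 ± 0.308, and Ttr, at 143 ± 7.33 against 0.352 ± 0.314, rose with them, as did Plat and Ptgds from a listed 0. Falls included Duoxa2, a maturation factor of dual oxidase, at 1.96 ± 3.4 against 142 ± 7.66, and the FGF-binding protein Fgfbp1 at 3.84 ± 5.44 against 213 ± 13. Inpp1, an inositol phosphatase, fell to 1.98 ± 3.43 against 67.5 ± 2.89. Prss50 and Stfa1 were listed at 0 in the treated libraries, and Tuba3a, Nmral1 and Psors1c2 had log2 changes of -4.54, -4.38 and -4.3.

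Of 25 measured primitive endoderm markers 23 rose and 1 fell at E5.0 (median log2 change 4.15, adjusted p = 6.94e-16). The endocytic adaptor Dab2 was at 526 ± 42.5 TPM against 6.53 ± 1.5 (log2 change 6.15, adjusted p = 1.76e-06) and the basement membrane collagen Col4a1 at 109 ± 11.6 against 0.789 ± 0.48. Among trophectoderm markers 8 of 18 fell and 1 rose (median log2 change -0.68, adjusted p = 6.87e-05). The signal Bmp4 was at 49 ± 22 against 245 ± 9.73 and the factor Elf5 at 17.9 ± 2.55 against 68.8 ± 5.84. Controls had Sox2 at 0.548 to 2.32 TPM, and whether they held trophectoderm was not tested. ATF4 and amino acid stress genes rose, 10 of 16 (median log2 change 1.12, adjusted p = 1.45e-05). Adjusted over the list alone, 13 rose and 1 fell. Examples were the stress factors Ddit3, at 556 ± 91.2 against 39.6 ± 6.28, and Nupr1, at 538 ± 41.6 against 45 ± 3.75, and the pseudokinase Trib3 at 216 ± 25.2 against 39.9 ± 3.7. In the autophagy and vesicle trafficking list 14 of 25 rose and 0 fell (median log2 change 0.76, adjusted p = 4.91e-05). The autophagosome protein Gabarap was at 388 ± 40.7 against 38.8 ± 1.41 and the lysosomal protein Lamp1 at 540 ± 84.7 against 144 ± 16. The primitive endoderm markers rose in the same libraries as these stress, autophagy and hypoxia genes.

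Glycolysis and hypoxia genes were higher, with 9 of 19 up and 1 down (median log2 change 0.43, adjusted p = 0.00139, but adjusted p = 0.0628 with an estimated correlation). The mitophagy receptor Bnip3 was at 480 ± 38.6 against 73.1 ± 14.2 and the hypoxia-induced Ndrg1 at 134 ± 11.5 against 30.5 ± 4.16. In the p53 list 7 of 21 rose and 1 fell (median log2 change 0.51, adjusted p = 0.0292, but adjusted p = 0.162 with an estimated correlation). Eda2r was at 88.7 ± 25.6 against 14.1 ± 1.38, Plk2 at 162 ± 19 against 43.4 ± 5.36 and, in the other direction, Perp at 52.7 ± 10.1 against 221 ± 13.2. The p53 call was lost without treated replicate 1 (adjusted p = 0.0808). Ribosome biogenesis genes were lower, 8 of 21 down and 1 up (median log2 change -0.49, adjusted p = 0.00139, but adjusted p = 0.236 with an estimated correlation). The nucleolar chaperone Npm1 was at 1790 ± 224 against 3360 ± 90. Core pluripotency genes were lower, 5 of 12 down and 1 up (median log2 change -0.79, adjusted p = 0.0292, but adjusted p = 0.157 with an estimated correlation). The Nodal co-receptor Tdgf1 fell to 39 ± 17 against 244 ± 10.1 and the chromatin factor Utf1 to 384 ± 53.6 against 1130 ± 21.8. The core call was lost without treated replicate 1 or 2 (highest adjusted p = 0.0766). Of 14 naive pluripotency genes 7 rose and 1 fell, and the list did not pass (adjusted p = 0.0621). The naive factors Tbx3 and Nanog were at 23.5 ± 4.21 against 0.505 ± 0.349 and 17.2 ± 7.18 against 2.37 ± 1.41. Formative genes moved both ways, 2 of 16 up and 3 down (list adjusted p = 0.115). The DNA methyltransferase Dnmt3b was at 35.7 ± 8.42 against 103 ± 7.36 and Otx2 at 38 ± 4.11 against 17.2 ± 5.6. Nodal pathway targets did not pass as a list (adjusted p = 0.0634), although the Nodal inhibitor Lefty2 fell to 0.0414 ± 0.0717 against 7.01 ± 1.91. Imprinted genes had 7 of 22 up and 3 down (list adjusted p = 0.777). The placental growth regulator Phlda2 was at 195 ± 14.9 against 1180 ± 65.7 and the noncoding RNA Rian at 17.5 ± 6.05 against 2.51 ± 0.72. The endoderm organiser genes Cer1 and Foxa2 rose, to 55.6 ± 11.4 TPM against a listed 0 and 16.5 ± 2.32 against 0.344 ± 0.537, and their gastrulation list had too few members for a test. Mitosis (2 up and 3 down of 20), germline (2 and 4 of 18), developmental Polycomb target (0 and 2 of 10) and Polycomb machinery genes (4 and 3 of 28) did not pass as lists, with adjusted p of 0.607, 0.0634, 0.267 and 0.546.

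Treated libraries had Ftl1 at 45208 to 47777 TPM against 22260 to 22934, and 11.4% to 11.7% of TPM in their 10 most abundant genes against 7.62% to 7.72%. Limma called 3023 of 10681 genes at E5.0, 1778 higher and 1245 lower, beside a median log2 change of 0.12 over all tested genes. With quantile normalization, which removes such a shift, 1256 were higher and 1540 lower. Without control replicates 1, 2 or 3 the count was 1785, 1674 and 1725.

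**Figure D2:**
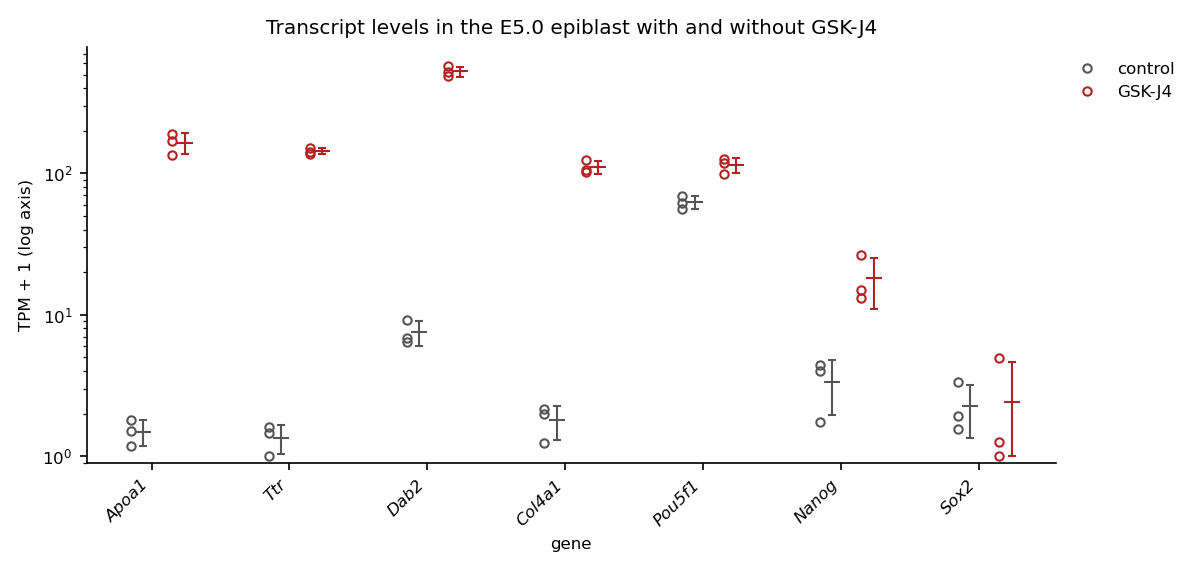
TPM + 1 on a log axis for 4 primitive endoderm markers and the pluripotency genes Pou5f1, Nanog and Sox2 in the 3 control and 3 GSK-J4 libraries at E5.0, with circles for libraries and bars for mean ± SD. Apoa1, Ttr, Dab2 and Col4a1 lay higher in each of the 3 GSK-J4 libraries than in any control, at means of 164, 143, 526 and 109 TPM. So did Pou5f1, at 98.8 to 126 TPM against 55.3 to 68.2.

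The Suz12 Eed double knockout asked what loss of Polycomb repressive complex 2, which places H3K27 methylation, does in Epi and PrE at E5.0. In Epi Prl3d1, placental lactogen 1 of trophoblast giant cells, was at 172 ± 20.9 TPM against 1.17 ± 0.605 (log2 change 6.35, adjusted p = 1.54e-04). The hormone secretin, Sct, rose to 293 ± 35.4 TPM against 3.71 ± 1.38 (log2 change 6.00, adjusted p = 3.6e-09). Plac1 rose to 833 ± 164 TPM against 27 ± 0.822 (log2 change 4.88, adjusted p = 4.85e-11) and the reproductive homeobox gene Rhox9 to 399 ± 20.9 against 13.2 ± 4.85. Prl2c5 rose to 56.7 ± 15.6 against 0.312 ± 0.54, the surface protein Cd7 to 55.2 ± 6.31 against 1.29 ± 1.37, and Prl7a1 and Rhox12 reached 55.3 and 28.0 TPM from a listed 0. Falls were smaller, with the protease Ddi2 at 1.23 ± 1.13 against 14.7 ± 5.05 and the carbonic anhydrase Car14 at 3.4 ± 3.37 against 22.4 ± 4.65. Qprt, an enzyme of NAD synthesis, fell to 6.25 ± 2.78 against 40.2 ± 8.32, and the germ cell RNA-binding protein Dnd1 to 3.87 ± 5.52 against 12.8 ± 2.31. Rab33a, Dtx1 and Ndufa4l2 also fell, by 2.41, 2.2 and 2.18 on the log2 scale, and Hba-x was listed at 0 in the knockout.

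In Epi 9 of 19 trophectoderm markers rose and 1 fell (median log2 change 1.3, adjusted p = 1.91e-14). Rhox6 was at 631 ± 26.5 against 41.2 ± 3.93. Whether trophoblast cells were collected was not tested. Formative and primed genes fell, 9 of 19 with 0 rises (median log2 change -1.09, adjusted p = 4.02e-09). They included Otx2 at 15 ± 6.55 against 42.9 ± 7.16, Dnmt3b at 86 ± 10.8 against 246 ± 49.5 and the growth factor Fgf5 at 27.5 ± 5.23 against 76 ± 16.6. Naive genes rose, 4 of 13 with 0 falls (median log2 change 0.54, adjusted p = 9.65e-06). The AKT coactivator Tcl1 was at 28.2 ± 9.04 against 4.87 ± 2.13, and the factors Klf4 and Klf2 were up by 1.30 and 1.21 on the log2 scale. Core pluripotency genes fell, 5 of 13 (median log2 change -0.92, adjusted p = 2.13e-05, but adjusted p = 0.162 with an estimated correlation), and 10 fell adjusted over the list alone. The RNA-binding protein Lin28a was at 9.5 ± 1.39 against 33.6 ± 5.71 and Sall4 at 149 ± 32.7 against 286 ± 88.4. Primitive endoderm markers rose, 6 of 16 (median log2 change 0.58, adjusted p = 7.74e-06, but adjusted p = 0.0942 with an estimated correlation). Cited1 was at 212 ± 26.2 against 68.1 ± 10.4 and Apoa1 at 43.5 ± 14.7 against 12.9 ± 4.45. Glycolysis and hypoxia genes were lower, 10 of 19 down and 1 up (median log2 change -0.63, adjusted p = 5.92e-05, but adjusted p = 0.235 with an estimated correlation). The glycolytic enzymes Pfkl and Pkm fell, to 46.6 ± 8.54 against 150 ± 48.3 and 893 ± 229 against 2120 ± 728. In the ribosome biogenesis list 3 of 21 fell (median log2 change -0.44, adjusted p = 5.92e-05, but adjusted p = 0.235 with an estimated correlation), with the rRNA methyltransferase Nop2 down by a log2 change of -1.22.

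Imprinted genes in Epi had 4 of 20 rises and 1 fall (median log2 change 0.03, adjusted p = 0.0118, but adjusted p = 0.417 with an estimated correlation), and the call was lost without knockout replicate 3 (adjusted p = 0.0517). The maternally expressed Phlda2 rose to 2280 ± 347 against 684 ± 131, Cdkn1c to 80.2 ± 32.9 against 23.1 ± 9.43 and H19 to 436 ± 79.7 against 176 ± 34.1. The paternally expressed Igf2 rose to 32.2 ± 14.1 against 10.2 ± 1.75. Of 19 measured developmental Polycomb targets 1 rose, Msx2 at 11 ± 1.73 against 1.82 ± 1.39, and 1 fell, Gbx2 by 1.30 on the log2 scale (list adjusted p = 0.451). The Nodal inhibitor Lefty1 rose to 22.6 ± 2.23 against 9.32 ± 5.64 while its list did not pass (adjusted p = 0.806). Gastrulation, p53, ATF4, mitosis, autophagy, germline and Polycomb machinery lists did not pass either (adjusted p of 0.673, 0.405, 0.361, 0.0658, 0.213, 0.183 and 0.251). Limma called 1027 of 11250 genes in Epi, 504 higher and 523 lower, with a median log2 change of -0.13 over all tested genes. The count was 643 without control replicate 1 and 604 without control replicate 2.

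In PrE the double knockout was compared at n = 3 with controls at n = 2. General measures differed, with Actb at 11649 to 15687 TPM against 39425 to 50018, Ftl1 at 37545 to 41891 TPM against 18360 to 22166, Rn45s at 2606 to 3806 TPM against 521 to 732, and 10720 to 11188 genes at 1 TPM or more against 9740 to 9871. The chemokines Ccl2 and Cxcl10 rose to 33 ± 11.4 against 0.0869 ± 0.123 and 22.6 ± 8.76 against 0.171 ± 0.0167, and the skeletal actin Acta1 to 36.1 ± 8.18 against 0.729 ± 1.03. The chaperone Clu rose to 55.2 ± 4.71 TPM against 2.46 ± 3.48 (log2 change 4.53, adjusted p = 5.13e-05) and Snapc2 to 25.5 ± 2.38 against 0.72 ± 1.02. Derl3, Sprr1a and Sct rose from a listed 0. The largest falls included Ogdhl, a 2-oxoglutarate dehydrogenase subunit, at 19.3 ± 5.75 against 134 ± 24.1, and the factor Sp8 at 8.22 ± 3.16 against 54.4 ± 19.9. The cell cycle inhibitor Cdkn1b fell to 27.4 ± 7.07 against 165 ± 43.6 and the glycine cleavage enzyme Amt to 208 ± 29.9 against 1186 ± 269. Ggact, Pla2g1b and Mir3966 also fell, and Slc24a5 was at 7.83 ± 4.91 against 461 ± 575.

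Of 21 p53 targets in PrE 13 rose and 0 fell (median log2 change 0.92, adjusted p = 7.19e-04, but adjusted p = 0.375 with an estimated correlation). The cell cycle inhibitor Cdkn1a was at 251 ± 36.3 against 81.2 ± 2.87, Phlda3 at 63.7 ± 18.8 against 7.96 ± 0.059 and the BH3 protein Pmaip1 at 14.1 ± 3.3 against 2.43 ± 0.552. ATF4 and amino acid stress genes rose, 13 of 17 (median log2 change 1.36, adjusted p = 7.18e-05, but adjusted p = 0.375 with an estimated correlation). Atf3 was at 97.1 ± 16.3 against 12.9 ± 0.356 and the glutathione-degrading Chac1 at 11.2 ± 3.08 against 0.521 ± 0.0947. Developmental Polycomb targets had 11 of 27 rises and 0 falls (median log2 change 0.94, adjusted p = 0.0381, but adjusted p = 0.375 with an estimated correlation). Hoxc9 was at 5.38 ± 0.72 against 0.386 ± 0.546 and the cell cycle inhibitor Cdkn2b at 11.6 ± 9.5 against 1.9 ± 2.68. Trophectoderm markers had 5 of 14 rises (median log2 change 0.77, adjusted p = 0.0381, but adjusted p = 0.375 with an estimated correlation). The adjusted p was 0.0521 with the replicate number as a block. Krt8 was at 664 ± 43.8 against 141 ± 38.4. Glycolysis and hypoxia genes had 11 of 19 rises and 1 fall (median log2 change 0.79, adjusted p = 0.0407, but adjusted p = 0.499 with an estimated correlation). Eno1 was at 1470 ± 64 against 531 ± 36.1. Core pluripotency genes were lower, 3 of 10 down and 1 up (median log2 change -0.36, adjusted p = 0.0021, but adjusted p = 0.375 with an estimated correlation), with Sall4 at 376 ± 49.9 against 976 ± 103. Of 9 gastrulation genes 1 fell, the homeobox gene Mixl1 at 64.1 ± 3.33 against 315 ± 41.2 (median log2 change -0.27, adjusted p = 0.0381, but adjusted p = 0.375 with an estimated correlation).

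The formative and primed list in PrE tested lower (adjusted p = 0.026, but adjusted p = 0.375 with an estimated correlation), against a median log2 change of 0.08. Its mean was -0.21, and Otx2 fell to 15.2 ± 0.606 against 31.9 ± 1.41. The Polycomb and H3K27 or H3K4 methylation machinery list, 3 of 27 up and 4 down, also tested lower (adjusted p = 0.0381, but adjusted p = 0.375 with an estimated correlation), against a median of 0.15 and a mean of 0.037. The demethylase Kdm6b was at 84.5 ± 11.3 against 184 ± 28.5. Both medians were below 0 with quantile normalization, at -0.34 and -0.29. Primitive endoderm markers had 7 of 27 rises and 0 falls without passing (adjusted p = 0.116, and 0.0118 with quantile normalization), with Sox17 at 47.2 ± 17.2 against 10 ± 3.35. Naive, Nodal, ribosome, mitosis, autophagy, germline and imprinted lists did not pass (adjusted p of 0.743, 0.26, 0.415, 0.26, 0.675, 0.26 and 0.814). Of imprinted genes, Igf2r fell to 56.7 ± 9.4 against 251 ± 32.9 and H19 rose to 98.6 ± 9.56 against 20.8 ± 0.211. Limma called 3023 of 11354 genes in PrE, 2435 higher and 588 lower, beside a median log2 change of 0.40 over all tested genes, and 1297 higher and 1029 lower with quantile normalization. The count was 1389 without control replicate 3. The Polycomb target, gastrulation, trophectoderm, glycolysis and machinery calls each ended with single libraries left out, among them knockout replicate 1 in each case, with highest adjusted p of 0.108, 0.132, 0.116, 0.0796 and 0.0716.

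The difference between the tissues was tested gene by gene. It passed for 2520 of 13172 genes, with 548 changing more upward in Epi and 1972 more upward in PrE, and for 812 and 959 with quantile normalization. The median difference over all genes was -0.45 on the log2 scale. Plac1 went from 27 to 833 TPM in Epi and from 91.9 to 110 TPM in PrE (difference 4.62, adjusted p = 4.71e-08). Prl3d1 went from 1.17 to 172 TPM in Epi (difference 6.54, adjusted p = 0.00197). In PrE its log2 change was -0.184 (adjusted p = 0.898), with knockout libraries at 92.4, 15.9 and 1.8 TPM against controls at 17.3 and 18 TPM. Without replicates 1, 2 or 3 the count was 762, 1428 and 78.

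The Zbtb17 knockout at E4.5 asked what loss of this factor does before implantation; its libraries are titled knockout while a treatment label reads dTAG. Limma called 6 of 4576 genes, all higher. Named by the rule were the aldose reductase Akr1b8 at 573 ± 224 TPM against a listed 0 (adjusted p = 0.0293), and the galectin Lgals1 at 2065 ± 488 TPM against 350.3 ± 84.3 (log2 change 2.56, adjusted p = 0.0293). The glutathione transferase Gsta1 rose to 955 ± 94.5 against 179 ± 38 and Ddah1, a dimethylarginine hydrolase, to 2681 ± 95.7 against 919 ± 197. The other rises, BC051665 and BC053393, fell outside the rule and were chosen after their values were seen. At an unadjusted p under 0.05 the count was 370. Trophectoderm and extraembryonic ectoderm markers were higher as a list with 0 of 6 members passing (median log2 change 2.65, adjusted p = 0.0338, but adjusted p = 0.477 with an estimated correlation). Plac1 was at 269 ± 73.6 TPM against 27.4 ± 47.4 (log2 change 5.91, adjusted p = 0.318). The list call was lost without control replicate 3 or knockout replicates 2 or 3 (highest adjusted p = 0.238). Ctsll3 was higher without passing (adjusted p = 0.0939). The count of 6 became 3 without control replicate 2, and 0 without control replicate 3 or any of the knockout replicates. Replicates in this table correlated at 0.576 to 0.622 across genes.

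At E5.0 the libraries of the Zbtb17 knockout stood apart from their controls in general measures too. They had 9225, 8806 and 7447 genes at 1 TPM or more, replicate 3 the fewest, against 9982 to 10434, and Actb at 24459 to 42082 TPM against 14304 to 19574. Ctsll3 rose to 375 ± 78.3 TPM against 0.0745 ± 0.129 (log2 change 8.44, adjusted p = 9.88e-30) and the keratinocyte protein Dmkn to 467 ± 92.5 against 3.47 ± 3.18. The myosin light chain Myl4 rose to 372 ± 81.6 against 1.92 ± 1.16, the prolactin family gene Prl5a1 to 594 ± 67.4 against 4.55 ± 1.47 and Sct to 228 ± 45.1 against 2.01 ± 0.769. Psg29, Ecm1 and Lbhd2 rose by 6.74, 6.69 and 6.59 on the log2 scale. Cer1, a secreted Nodal and BMP antagonist, was at a listed 0 TPM against 93.5 ± 29.4 (adjusted p = 1.33e-25). Uridine phosphorylase Upp1 fell to 0.597 ± 0.613 against 139 ± 12.1 and the lactate dehydrogenase Ldhb to 2.84 ± 2.89 against 211 ± 25.1. The cobalamin factor Mmadhc fell to 1.54 ± 2.54 against 108 ± 27.2 and the glypican Gpc3 to 0.566 ± 0.358 against 70.1 ± 17.1. Vps72 and Pla2g1b fell by 5.79 and 5.75 on the log2 scale, and Tspan7 was listed at 0 in the knockout.

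Formative and primed genes fell in the E5.0 knockout, 10 of 15 with 0 rises (median log2 change -1.69, adjusted p = 4.97e-06). Fgf5 was at 0.035 ± 0.0607 against 29.8 ± 10.6 and Otx2 at 0.0424 ± 0.0735 against 27 ± 6.92. Core pluripotency genes fell, 10 of 13 (median log2 change -1.08, adjusted p = 1.87e-04). Dppa2 was at 24.9 ± 21.2 against 70.2 ± 13.3. Of 5 gastrulation genes 3 fell (median log2 change -1.86, adjusted p = 2.1e-05), including Lhx1 at 0.00475 ± 0.00822 against 25 ± 5.78. Trophectoderm markers rose, 9 of 17 with 0 falls (median log2 change 1.14, adjusted p = 5.33e-07). Prl3d1 rose to 2020 ± 600 against 69.3 ± 3.27 and the trophoblast factors Gata2 and Ascl2 to 23 ± 17.4 against 2.01 ± 1.06 and 37.1 ± 14.4 against 6.02 ± 1.93. Krt8 was at 3520 ± 597 against 833 ± 166. Naive genes were higher, 6 of 12 up and 1 down (median log2 change 0.72, adjusted p = 0.00244). The threonine dehydrogenase Tdh was at 24.2 ± 13.9 against 5.24 ± 1.68 and Esrrb lower at 1.52 ± 1.57 against 6.27 ± 2.02. Mitosis genes fell, 8 of 20 (median log2 change -0.4, adjusted p = 0.00188), such as the spindle protein Nusap1 with a log2 change of -2.2. Glycolysis and hypoxia genes were lower, 12 of 18 down and 2 up (median log2 change -0.63, adjusted p = 6.39e-04, but adjusted p = 0.0861 with an estimated correlation), with Pdk1 at 0.0542 ± 0.0939 against 4.07 ± 2.31. Primitive endoderm markers had 7 of 25 rises and 2 falls (median log2 change 0.43, adjusted p = 0.0356, but adjusted p = 0.0861 with an estimated correlation), and did not pass when adjusted over the whole screen (0.0503, and 0.124 with an estimated correlation). The endocytic receptor Lrp2 was at 15.7 ± 6.85 against 1.64 ± 0.638 and Apoa1 at 4.95 ± 8.25 against 45.5 ± 8.11.

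Polycomb target, Nodal, p53, ATF4, ribosome, autophagy, germline, imprinted and machinery lists did not pass in the E5.0 knockout (adjusted p of 0.707, 0.372, 0.451, 0.323, 0.775, 0.123, 0.977, 0.372 and 0.755). Among their members, the meiosis gene Sycp3 rose to 170 ± 19.2 against 9.33 ± 2.29 and Cdkn1a to 275 ± 26.3 against 132 ± 22.2. Limma, with the spread shared over the screen, called 2978 of 9815 genes, 1029 higher and 1949 lower, beside a median log2 change of -0.15 over all tested genes. The 6 libraries of its own batch alone gave 671, 259 higher and 412 lower, of which 666 were in both. Simulated libraries with no change and each group's own spread gave 840 calls in the shared fit.

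The dTAG degron, directed at Zbtb17 protein, whose level is not measured here, was profiled at E5.0. The treated libraries again had higher Ctsll3, at 238 ± 11.8 TPM against 0.0578 ± 0.1 (log2 change 7.82, adjusted p = 1.8e-07). The galectin Lgals2 rose to 72.1 ± 10.1 against 0.584 ± 1.01, Tcl1 to 31 ± 0.285 against 0.0337 ± 0.0585 and Ttr to 141 ± 18.9 against 3.95 ± 1.92. The cytoskeletal Septin11 rose to 57.2 ± 5.79 against 1.25 ± 0.528 and the water channel Aqp8 to 36.9 ± 20.1 against 1.12 ± 1.95. The apolipoproteins Apoa4 and Apom rose by 4.66 and 4.27 on the log2 scale. Some placental prolactin genes fell and others, Prl2a1 and Prl5a1, rose, by 3.46 and 2.27 on the log2 scale. Prl3d1 was at 4.47 ± 2.3 TPM against 324 ± 42.9 (log2 change -5.99, adjusted p = 4.52e-06). Prl3d2 was at 1.15 ± 1.14 against 156 ± 17.5 and Prl3d3 at 0.218 ± 0.202 against 99.3 ± 3.25. Prl4a1 and the cathepsin Cts7 were listed at 0 in the treated libraries. Car14 fell to 3.34 ± 2.98 against 38.1 ± 8.09, Tspan7 to 0.0369 ± 0.0639 against 12.6 ± 4.42 and the globin Hba-a1 to 0.0111 ± 0.00815 against 26.7 ± 27.8.

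Primitive endoderm markers rose with the degron, 11 of 22 with 0 falls (median log2 change 1.39, adjusted p = 2.66e-09), and 15 rose and 1 fell adjusted over the list alone. Dab2 was at 75.5 ± 13.3 against 5 ± 0.991 and the proteoglycan Srgn at 75.4 ± 6.14 against 4.51 ± 2.89. Trophectoderm and extraembryonic ectoderm markers were higher, 11 of 17 up and 1 down (median log2 change 0.87, adjusted p = 8.35e-05, but adjusted p = 0.177 with an estimated correlation). Plac1 was at 357 ± 17.5 against 81.9 ± 4.06 and Gata3 at 53.4 ± 14.9 against 11.3 ± 5.55, and Prl3d1 was the member that fell. Naive genes were higher, 4 of 11 up and 1 down (median log2 change 0.64, adjusted p = 0.016, but adjusted p = 0.253 with an estimated correlation). The nuclear receptor Nr0b1 was at 41.7 ± 15.4 against 3.22 ± 2.06, and Dppa3 fell to 7.46 ± 4.96 against 25.9 ± 6.61. The naive call was lost without dTAG replicate 1 (adjusted p = 0.0935). The blood, stromal and fibroblast list tested lower with 2 of 5 down (median log2 change -0.94, adjusted p = 0.0451, but adjusted p = 0.253 with an estimated correlation), the globin Hba-a1 and the stromal proteoglycan Dcn. That call was lost without control replicate 55 or dTAG replicates 1 or 3 (highest adjusted p = 0.207) and with quantile normalization (0.0707). Formative genes moved both ways, with Lef1 at 40.2 ± 12.1 against 14.3 ± 4.26 and Dnmt3b at 114 ± 6.61 against 208 ± 30.2 (list adjusted p = 0.36). Core, Polycomb target, gastrulation, Nodal, p53 and ATF4 lists did not pass (adjusted p of 0.976, 0.463, 0.236, 0.86, 0.36 and 0.0725). Nor did glycolysis, ribosome, mitosis, autophagy, germline, imprinted and machinery lists (0.283, 0.976, 0.236, 0.236, 0.877, 0.795 and 0.926). Limma called 1246 of 10658 genes, 767 higher and 479 lower, beside a median of 0.14 over all tested genes, and 515 higher and 526 lower with quantile normalization. The count was 800, 797 and 804 without control replicates 55, 56 and 57, 807 without dTAG replicate 1 and 730 without dTAG replicate 3.

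**Figure D3:**
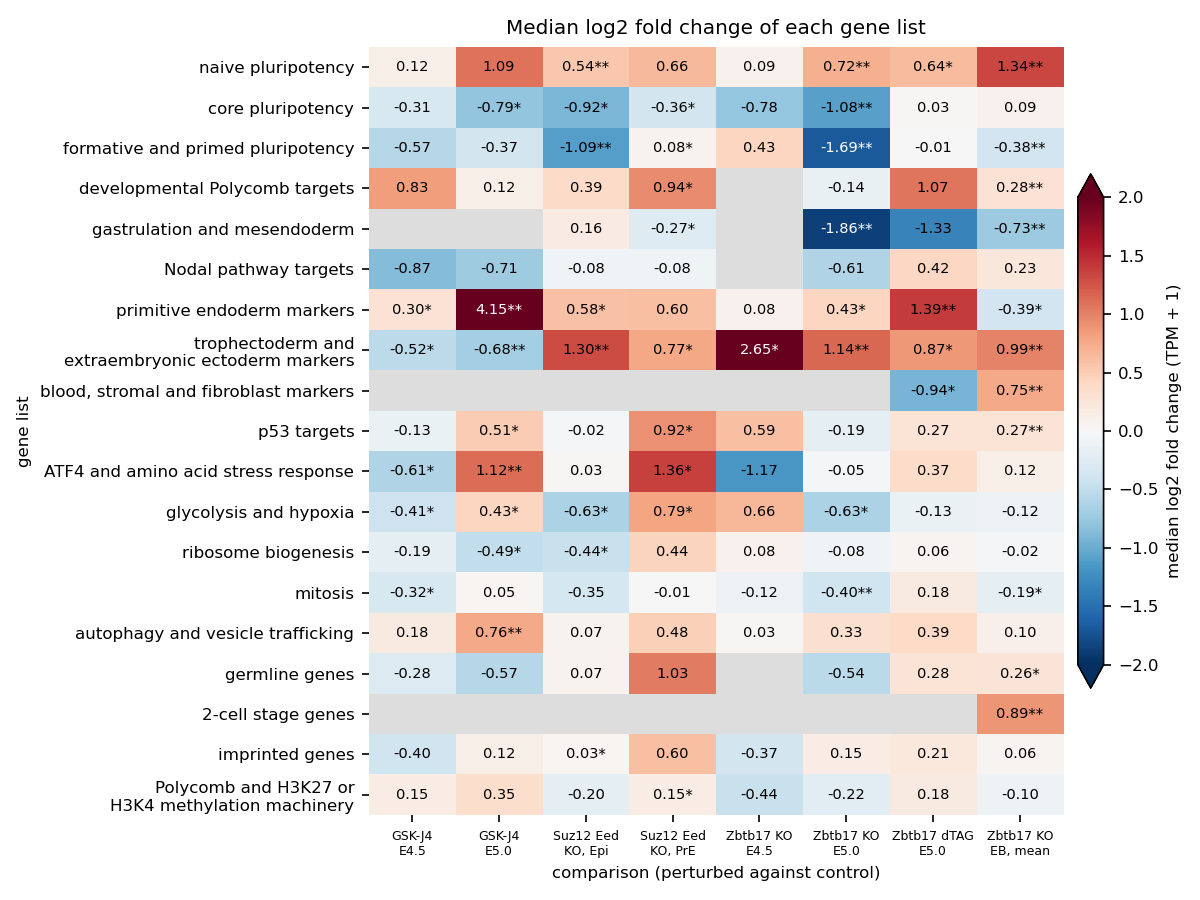
Median log2 change (TPM + 1) of each gene list in 8 comparisons, perturbed against control; 1 asterisk marks adjusted p under 0.05 with the preset correlation, a second one the same with an estimated correlation, and grey marks lists with too few measured members. Primitive endoderm markers had a median of 4.15 with GSK-J4 at E5.0, and formative genes -1.69 in the Zbtb17 knockout at E5.0.

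In EB the Zbtb17 knockout was followed on days 0 to 3 with 2 libraries per genotype and day. Knockout titles share a label, so cell line effects were not separated. The table has no gene names, so these rest on its row order. The 2 libraries of a group correlated at 0.992 to 0.994, so their spread may be technical. On day 3 gastrulation genes were low and naive genes high in the knockout. The mesendoderm factor Eomes was at 9.48 ± 0.598 TPM against 86.7 ± 2.02 (log2 change -3.06, adjusted p = 3.86e-10) and the endoderm factor Foxa2 at 1.17 ± 0.0353 against 23.1 ± 0.156. Brachyury, T, was at 10.7 ± 0.977 TPM against 76.8 ± 2.51, and the growth factor Fgf8 at 32.8 ± 4.06 against 199 ± 4.68. The naive factor Esrrb rose to 55.6 ± 1.89 TPM against 2.78 ± 0.275 (log2 change 3.91, adjusted p = 7.6e-12), Zfp42 to 207 ± 0.35 against 11 ± 0.128 and Nr0b1 to 53.6 ± 0.133 against 1.91 ± 0.576. Rhox6 rose to 67.8 ± 7.2 against 1.73 ± 0.586, the galectin Lgals3 to 41.4 ± 0.489 against 1.08 ± 0.244 and the cell cycle inhibitor Cdkn2a to 52.9 ± 1.89 against 12.2 ± 1.63. The chemokine Cxcl12 fell to 6.28 ± 0.0596 against 60.8 ± 0.843. Dnmt3b fell to 372 ± 6.36 against 970 ± 19.9 and its cofactor Dnmt3l rose to 282 ± 10.6 against 57 ± 3.48. Nanog was lower, at 143 TPM against 277.

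**Figure D4:**
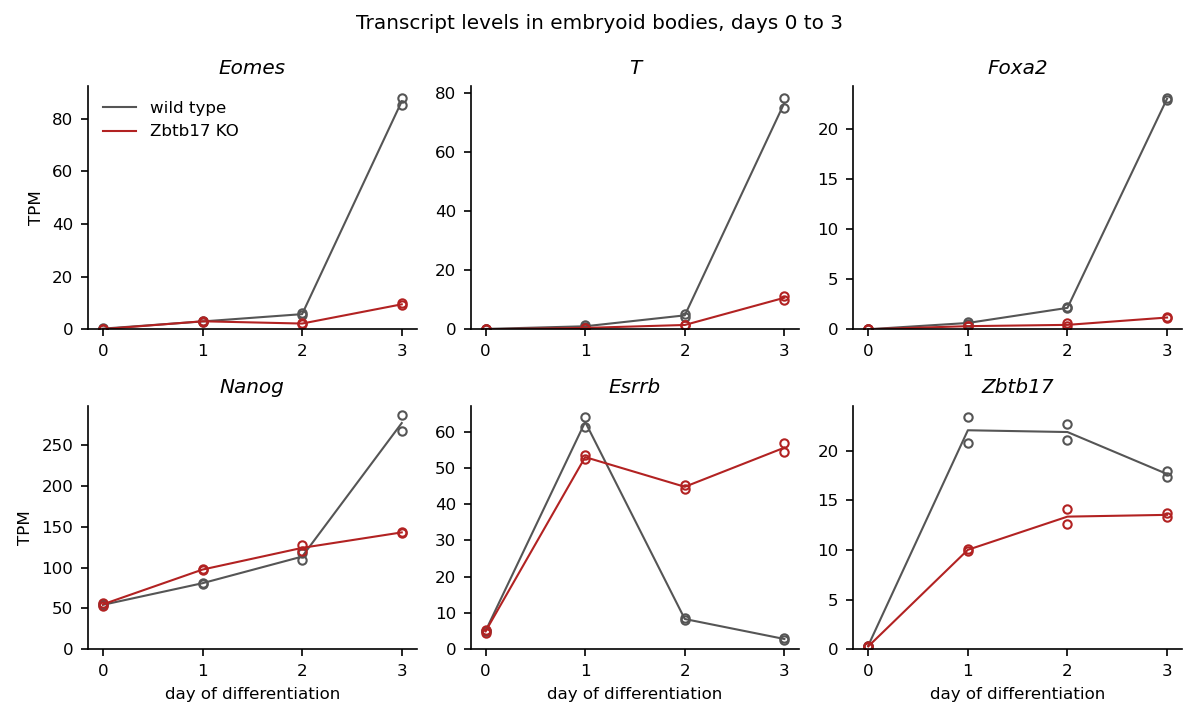
TPM of Eomes, T, Foxa2, Nanog, Esrrb and Zbtb17 in wild-type and Zbtb17 knockout embryoid bodies against the day of differentiation, with circles for the 2 libraries per genotype and day and lines through their means; gene names rest on row order. On day 3 Eomes was at 9.48 TPM in the knockout and 86.7 TPM in wild type.

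Over the 4 days together, 15 of 16 naive genes rose and 1 fell (median log2 change 1.34, adjusted p = 1.02e-11), with Dppa3 and Klf2 up by 2.17 and 1.69 on the log2 scale. Of 11 gastrulation genes 10 fell (median log2 change -0.73, adjusted p = 4.12e-06). Formative genes were lower, 12 of 21 down and 1 up (median log2 change -0.38, adjusted p = 3.64e-05). Trophectoderm markers were higher, 14 of 16 up and 1 down (median log2 change 0.99, adjusted p = 9.88e-08). Among them were Plac1 at 9.79 against 0.319 and Rhox6 at 36.6 against 2.54. All 11 measured 2-cell stage genes rose (median log2 change 0.89, adjusted p = 9.88e-08), with Tcstv3 up by 1.53. Developmental Polycomb targets were higher, 44 of 69 up and 7 down (median log2 change 0.28, adjusted p = 7.57e-05), with Hoxb9 up by 0.92 and Olig1 down at -0.93. The p53 list had 15 of 22 rises and 1 fall (median log2 change 0.27, adjusted p = 2.75e-05), with Cdkn1a up by 1.03. In the blood, stromal and fibroblast list 8 of 11 rose and 1 fell (median log2 change 0.75, adjusted p = 1.3e-04), and the collagens Col1a1 and Col1a2 were up by 1.54 and 1.35, although on day 1 the list was lower, 4 of 8 down (adjusted p = 0.0182, and 0.0887 with an estimated correlation). Mitosis genes fell, 17 of 20 (median log2 change -0.19, adjusted p = 4.92e-06, but adjusted p = 0.0862 with an estimated correlation), with the kinetochore protein Cenpf at -0.53. Germline genes were higher, 10 of 20 up and 2 down (median log2 change 0.26, adjusted p = 0.0199, but adjusted p = 0.0795 with an estimated correlation).

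Primitive endoderm markers in EB were lower, 18 of 26 down and 7 up (median log2 change -0.39, adjusted p = 0.0243, but adjusted p = 0.0533 with an estimated correlation). With quantile normalization the list did not pass (adjusted p = 0.119), and Ttr had a log2 change of -1.48. On day 0 the list was higher, 8 of 10 up and 1 down (adjusted p = 0.0205), and on day 1 lower, 12 of 20 down and 3 up (0.00674), neither with an estimated correlation (0.0932 and 0.0772). The remaining EB lists did not pass over the 4 days, with adjusted p of 0.399 for core pluripotency, 0.14 for Nodal, 0.0511 for ATF4, 0.0713 for glycolysis, 0.52 for ribosome, 0.0634 for autophagy, 0.938 for imprinted and 0.0706 for machinery genes, although the imprinted H19 rose by 2.2. With quantile normalization ATF4, autophagy and glycolysis passed, at 0.0433, 0.0255 and 0.000411. Other named genes were the serum protein Gc at 18.9 against 0.293, Krtdap at 33.5 against 1.9, Xlr4a and Xlr5c among rises. Falls included Ankrd31 at 0.286 against 12.7, the neuropeptide Npy at 1.07 against 9.64 and the activin antagonist Fst at 8.33 against 34.7. Spink1, Mid1 and Cubn fell by 1.34, 1.18 and 1.17 on the log2 scale.

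Single days differed in general measures too. Day 0 libraries had 5970 and 5986 genes at 1 TPM or more in wild type and 6966 and 6983 in the knockout, with the pre-ribosomal RNA Rn45s at 1042 and 1052 TPM against 488 and 515, and Actb at 291 and 288 TPM against 464 and 473. Their 10 most abundant genes held 33.2% to 36% of the TPM. Wild-type Pou5f1 was at 14.5 TPM, against 2390 TPM on day 1. On day 0, Dppa3 was at 91.6 ± 3.24 TPM against 5.92 ± 2.16 (log2 change 3.78, adjusted p = 1.24e-08). That day 19 of 19 glycolysis and hypoxia genes rose (median log2 change 0.9, adjusted p = 1.15e-08), and the naive list did not pass (adjusted p = 0.89). On day 1, Krt8 was at 119 ± 4.03 TPM against 8.78 ± 1.25 (log2 change 3.62, adjusted p = 8.43e-10) and 14 of 16 trophectoderm markers rose (median log2 change 1.63, adjusted p = 1.24e-11). The endoderm factor Gata6 was at 1.94 ± 0.241 against 14.8 ± 0.562, and the naive list did not pass (0.237). On day 2, Plac1 was at 21.1 ± 0.907 against 0.613 ± 0.197, 15 of 16 naive genes rose (median log2 change 1.66, adjusted p = 5.93e-17) and 8 of 10 gastrulation genes fell (median log2 change -1.02, adjusted p = 2.94e-04). On day 3, 10 of 10 gastrulation genes fell (median log2 change -2.51, adjusted p = 8.3e-07) and 11 of 11 2-cell stage genes rose (median log2 change 2.12, adjusted p = 2.43e-10), with Zscan4c at 70 ± 4.02 against 13.7 ± 0.573. Of 19 glycolysis genes 15 fell and 1 rose (median log2 change -0.6, adjusted p = 5.86e-06).

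Limma called 8102 of 14795 EB genes for the mean over days, 4125 higher and 3977 lower, of which 267 reached a 2-fold change. Day 0 gave 4106 of 6864 (3282 higher and 824 lower, median 0.23 over all tested genes), and 1796 higher and 1504 lower with quantile normalization. Days 1, 2 and 3 gave 4910, 5847 and 7363, and the genotype effect differed between days for 8887 genes. Later days had 12807 to 13512 genes at 1 TPM or more. Simulated groups with no change gave 68 calls on day 3.

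The Zbtb17 perturbations shared genes across tables that share no control libraries. Of 9195 genes tested in both, the E5.0 knockout and the degron called 506 in the same direction, 221 higher against 70.7 expected by chance and 285 lower against 85.8. Opposite directions held 103 genes against 185 by chance. The E5.0 knockout and EB shared 1134 genes against 816 by chance, and the degron and EB 616 against 334. Across all genes tested in both, log2 changes correlated at 0.259, 0.169 and 0.194 in these 3 pairs. Ctsll3 rose in the E5.0 knockout (log2 change 8.44) and the degron (7.82), and Prl2a1 (5.78 and 3.46), Prl5a1 (6.78 and 2.27) and Aqp8 (3.28 and 4.40) did likewise. Tspan7 (-5.68 and -3.65) and Mmadhc (-5.85 and -1.82) fell in both. Sct, Dmkn and Ecm1 rose in the E5.0 knockout and in EB, and Lgals2 rose in both E5.0 comparisons and fell by 0.71 in EB. Prl3d1 rose in the E5.0 knockout (4.81) and fell with the degron (-5.99), a difference between tables that was not tested.

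The knockout screen asked which chromatin and transcription factors shape the E5.0 epiblast transcriptome, although labels of batch 8 give both E5.0 and day 6.0. For Ezh2, the H3K27 methyltransferase, 2767 genes were called, and 1236 within its batch alone. Its knockout raised Apoa1 to 969 ± 107 TPM against 4.84 ± 3.35 (log2 change 7.56, adjusted p = 2.09e-20), the retinol carrier Rbp4 to 390.4 ± 50.3 against 4.27 ± 4.52 and Sct to 373 ± 37.6 against 5.95 ± 6.93. Apom rose to 79.4 ± 9.43 against 0.208 ± 0.361, and Prl3d1 fell to 3.33 ± 2.39 TPM against 1282 ± 131 (log2 change -8.35, adjusted p = 6.11e-19) with Prl7a1, Prl3d2 and Prl3d3. The Suz12 knockout changed 2425 genes, with Prl2c5 at 669.9 ± 54.4 against 0.0416 ± 0.072, Sct at 3191 ± 78.7 against 5.83 ± 2.77 and Prl2a1 at 364 ± 13.1 against 0.0518 ± 0.0897. Serpinb9d went from a listed 0 to 223 TPM, Bmp4 fell to 6.58 ± 3.97 against 135 ± 11.7 and Ccl2 and Nts were listed at 0. The knockout of Elf5, a trophoblast stem cell factor, changed 2531 genes, with Ctsll3 at 724 ± 46.5 against 0.0444 ± 0.0769 and the annexin Anxa1 at 288 ± 74.5 against 6.79 ± 7.41. The trophoblast factor Hand1 fell to 6.16 ± 2.97 against 216 ± 13.3 (adjusted p = 3.65e-31) and Duoxa2 to 4.36 ± 3.96 against 202 ± 31.4. The knockout of Ets2, a trophoblast factor, changed 2354 genes, with Ctsll3 at 886 ± 91.4 against 0.0444 ± 0.0769 and Anxa1 at 458 ± 113 against 6.79 ± 7.41, and Ccl2, Cthrc1 and Chac1 listed at 0. The libraries labelled Cxxc1 KO changed 2271 genes, with Adh1 from a listed 0 to 475 TPM and Prl3d1 at 359.8 ± 121 against 2.99 ± 3.05, and Cer1 listed at 0 against 19.6 TPM.

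Bend3, a heterochromatin-associated repressor, was targeted in 2 batches. In batch 8 the comparison gave 2881 genes. Fabp3, a fatty acid binding protein, rose to 54 ± 5.14 TPM against 2.75 ± 1.93 (log2 change 3.98, adjusted p = 1.79e-55) and Npy to 50.5 ± 5.48 against 1.25 ± 2.17. The germ cell genes Dazl and Sohlh2 fell to 1.6 ± 0.957 against 59.8 ± 10.4 and 1.09 ± 0.342 against 71.7 ± 8.53. The X inactivation RNA Xist was at 18.5 ± 8.49 TPM against 0.0093 ± 0.0161 and the Y-linked Eif2s3y at a listed 0 TPM against 62.8 ± 20.1, so sex-linked transcripts differed between these groups. In batch 7 the libraries labelled Bend3 KO gave 3541 calls with the shared spread and 24 within the batch, 22 of them in both. The ubiquitin hydrolase Uchl1 passed in each, at 254 ± 60.7 TPM against 6.9 ± 6.06 (log2 change 5.23, adjusted p = 7.25e-15) and adjusted p = 0.00764 within the batch. Srgn, at 0.247 ± 0.427 against 52.4 ± 8.71, did not pass within it (0.165). Libraries of batch 7 had 186890 to 316030 TPM of the 45S pre-ribosomal RNA Rn45s, and simulated libraries with no change gave a mean of 1882 calls for this knockout in the shared fit and 0 within the batch.

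Over 39 tested knockouts limma gave 41540 calls, 20677 higher and 20863 lower, of which 24725 were also called within the batch alone. With the shared spread at least 100 genes changed in 35 knockouts and over 1000 in 15, and at least 100 in 38 within batches and in 32 by both fits. The H3K27 demethylase Kdm6b changed 2260 genes, 592 higher and 1668 lower, its relative Kdm6a 959, the elongation factor subunit Nelfb 2224, Mcrs1 1768, the imprint keeper Zfp57 1714, the general factor Gtf2b 1650 and Tfap2c 1412. The fewest with the shared spread were 75 for Ovol2, 62 for Wt1, 49 for Junb and 37 for Hsf2. There simulated libraries with no change gave 5, 6, 27.2 and 25.4. Simulated screens with no change gave a mean of 6483 calls with the shared spread and 917 within batches, with 751 for Ezh2 and 285 for Kdm6b in the shared fit.

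**Figure D5:**
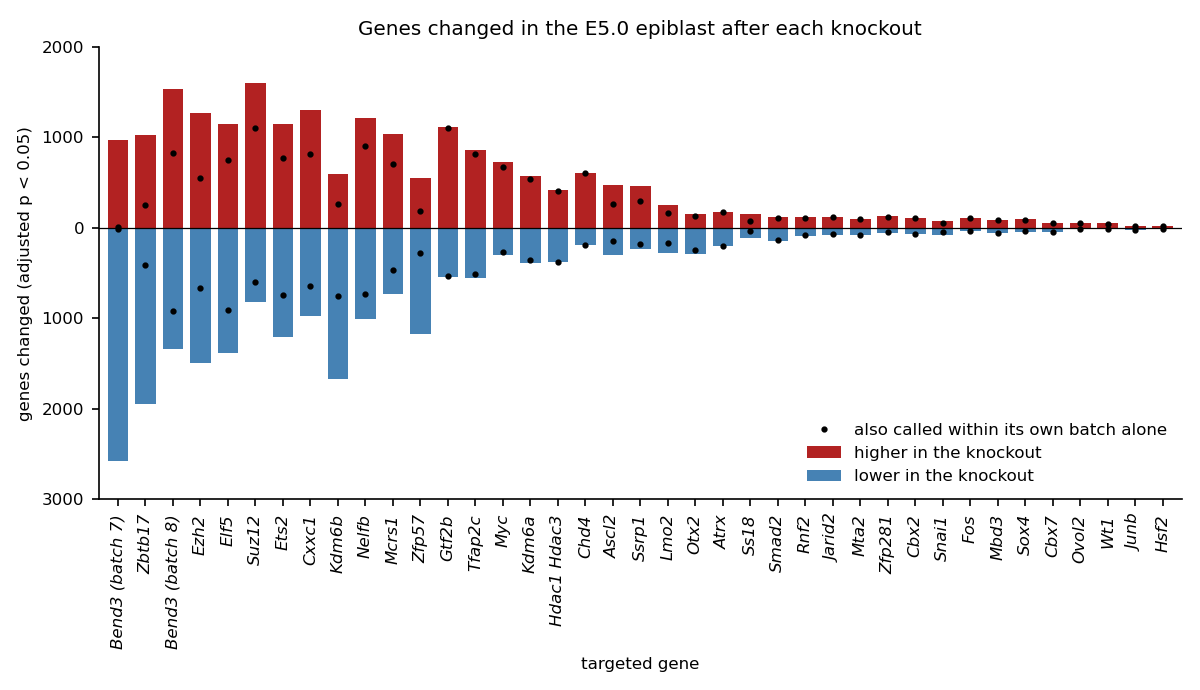
Bars show genes changed (adjusted p under 0.05) after each knockout against its batch controls, higher above and lower below 0, and points the genes also called in the batch alone. The libraries labelled Bend3 KO in batch 7 have 3541 calls, 22 of them called in both fits.

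Extra-embryonic markers differed from controls in many knockouts. The primitive endoderm list was higher in 19 and lower in 7 of 39 knockouts (17 and 6 with an estimated correlation). It was highest for the nucleosome remodeller Chd4, with 20 of 25 members up and 2 down (median log2 change 3.28, adjusted p = 3.12e-52), followed by Mcrs1 (median 2.78, 21 of 25 up) and Nelfb (2.59, 18 of 24 up). Nelfb libraries had Ftl1 at 40460 to 47322 TPM against 15519 to 16333, and those of Mcrs1 Rn45s at 10954 to 12297 TPM against 4318 to 4364. It was lower for the repressor Snai1, with 15 of 22 down and 1 up (-1.54, adjusted p = 2.81e-35), and Tfap2c (-1.13, 13 of 19 down). Of the wider set of genes enriched in control PrE libraries, 73 of 154 rose and 1 fell in the Chd4 knockout, 76 of 151 rose and 11 fell for Mcrs1, 59 of 136 and 8 for Nelfb, 97 of 149 rose and 1 fell for Ezh2, and 44 of 141 rose with the degron. Trophectoderm markers were higher in 19 and lower in 8 (18 and 6). The Elf5 knockout had a median of -1.20 and 9 of 17 down (adjusted p = 1.83e-05). Formative genes were higher in 6 and lower in 11 (5 and 10), with 9 of 16 up in the Tfap2c knockout (median 1.30, adjusted p = 2.63e-09). Naive genes were higher in 8 and lower in 5 (7 and 4), with 8 of 15 up in the libraries labelled Cxxc1 KO (median 1.29, adjusted p = 4.58e-05). Developmental Polycomb targets were higher in 2 of 38 knockouts, Ezh2 with 6 of 15 up (median 0.89, adjusted p = 0.026) and the Polycomb ligase Rnf2 with 4 of 19 up (0.46, 0.000283), and lower in 1. Imprinted genes were higher in 1, Suz12, with 12 of 25 up and 2 down (median 0.81, adjusted p = 0.000271), and lower in 3.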

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

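The tests of the differences below were planned. By limma's tests of the difference, the Suz12 Eed double knockout effect differed between Epi and PrE for 2520 genes. The Zbtb17 effect in EB differed between days for 8887. No group had 4 to 10 samples, so single libraries were not tested for standing apart.

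Genes that changed more upward in Epi included placental ones. Beside Prl3d1 (difference of log2 changes 6.54, adjusted p = 0.00197) and Plac1 (4.62, 4.71e-08), Prl2c5 differed by 5.49 (3.85e-05). Prl5a1 went from 1.5 to 36.9 TPM in Epi and from 1.92 to 0.0881 TPM in PrE (5.30, 4.06e-05). Rhox12 (4.8, 4.46e-05), Prl3d2 (4.33, 0.00907) and the serpin Serpinb9e (4.14, 4.46e-05) also differed. Slc24a5 went from 23.3 to 54.3 TPM in Epi and from 461 to 7.83 TPM in PrE (5.48, 0.00724). Prl2c5, Rhox12 and Serpinb9e were listed at 0 in each PrE group, so their differences depend on the 1 added to each TPM.

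Genes that changed more upward in PrE included the stress factor Gdf15, from a listed 0 to 15 TPM in PrE and from 3.24 to 2.14 TPM in Epi (difference -4.35, adjusted p = 0.000126), and the chemokine Ccl2 (-4.52, 0.000201). The cyclin Ccnd3 went from 0.775 to 22.8 TPM in PrE and from 111 to 64 TPM in Epi (-4.54, 0.000818). Hmga1b went from 0.596 to 12.6 TPM and from 278 to 88.4 TPM (-4.68, 0.000464), and Tmem238 from 3.96 to 39 TPM and from 58.7 to 24.7 TPM (-4.33, 0.000241). Ddi2 went from 0.277 to 4.63 TPM and from 14.7 to 1.23 TPM (-4.79, 0.00077). The secretory pathway genes Cpe (-4.69, 0.00223) and Derl3 (-4.88, 0.000676) rose in PrE from a listed 0.

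As lists, trophectoderm markers (adjusted p = 2.12e-05), naive genes (0.0045), p53 targets (0.00522), ATF4 genes (0.00189), glycolysis genes (5e-04) and ribosome biogenesis genes (0.00283) differed between the tissues with the preset correlation. With an estimated correlation 0 of these 6 passed, at 0.355 to 0.445. Leaving out replicate 1 or 3 leaves PrE 1 control library, and the count of 2520 became 762 and 78. Without replicate 2 it was 1428. With quantile normalization 812 genes changed more upward in Epi and 959 in PrE, so the imbalance between the directions depended on the scale of the values. Why the tissues differed was not tested.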

How the results depend on the processing

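Tests added after the data were seen were the libraries kept separate, batch 7 and Zbtb17 knockout replicate 3 left out, calls in both screen fits, EB days 1 to 3 alone, the crossed EB pairing, EB libraries left out singly, targets in their own batch and X and Y genes left out; the others were planned. Of 271 alternative values of 19 results, 221 lay within 1.5 times the reported value and 50 did not. The depth of the libraries is unknown, so what depth limits was not assessed. Of 258 named genes with a call, members named for a list aside, 215 kept it in each alternative run, 36 lost it with a library left out, 20 with the pseudocount, 15 with the block, 4 with quantile normalization, and 0 reversed.

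Requiring a 2-fold change lowered counts by construction, to 76 for GSK-J4 at E4.5, 611 in Epi, 584 for dTAG, 25963 in the screen, 267 for the EB mean, 345, 393, 776 and 1213 on EB days 0 to 3 and 2246 for the differences between days. Without the filter, GSK-J4 at E4.5 gave 19, the Zbtb17 knockout at E4.5 3 and dTAG 781. With a pseudocount of 0.1 the Zbtb17 knockout at E4.5 gave 0 by limma, against 6 with a pseudocount of 1, where 370 had an unadjusted p under 0.05. EB days 1 and 2 gave 2934 and 3784. Quantile normalization gave 2880 and 3645 on EB days 1 and 2 and 5918 for the differences between days. The Zbtb17 knockout at E5.0 gave 1300 with library weights and 671 in the same batch only. Calls in both screen fits were 24725. With an estimated correlation 189 list tests passed against 296. The overlap of the Zbtb17 perturbations was 2806 with an unadjusted p in both against 1690. Except for the 2-fold minimum, the cause was not tested.

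With single libraries left out, counts ran from 39 to 60 for GSK-J4 at E4.5, 1674 to 3612 at E5.0, 604 to 855 in Epi, 1389 to 2612 in PrE, 0 to 9 for the Zbtb17 knockout at E4.5 and 730 to 880 for dTAG. For the difference, leaving out a replicate number in all 4 groups gave 78 to 1428. A lone library left in a group was assumed to vary like the other groups. In EB, leaving out a replicate number leaves no residual degrees of freedom, so single libraries were left out.

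With the replicate number as a block, the Zbtb17 knockout at E4.5 gave 0 and the other counts lay within 1.5 times. They were 87 for GSK-J4 at E4.5, 2548 at E5.0, 1209 in Epi, 2739 in PrE, 2468 for the difference, 3274 for the Zbtb17 knockout at E5.0 and 47959 in the screen. EB gave 8029 for the mean, 4085, 4800, 5765 and 7294 on days 0 to 3 and 8767 for the differences between days. List tests gave 299 calls, against 292 in the same tables without the block, and targets 10 falls. Beside the ribosome list at E4.5 and the trophectoderm list in PrE, the block moved the naive list with GSK-J4 at E5.0 to 0.0378, the ATF4 list in EB to 0.0461 and the primitive endoderm list of the Zbtb17 knockout, adjusted over the screen, to 0.0387 from 0.0503. It changed no other list call in these comparisons, and calls of the other screen knockouts were only counted. EB day 0 numbers correlated at -0.169, and the crossed pairing gave 4067 calls. No paired analysis was possible because dTAG controls are numbered 55 to 57 and treated libraries 1 to 3.

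With quantile normalization of EB some directions reversed. On day 0 these were Etv5 (-0.093 from 0.17), Fbl (-0.0059 from 0.17), Ncl (-0.012 from 0.24), Top2a (-0.10 from 0.16), Tpx2 (-0.081 from 0.19) and Trp53inp1 (-0.014 from 0.24), and for the mean Aldoa (-0.021 from 0.074) and Slc2a3 (-0.011 from 0.097). In the Zbtb17 knockout at E5.0, Ccng1 was at 0.023 from -0.45 without knockout replicate 3, and L1td1 at 0.0015 from -1.55 without replicate 3 of both groups. The cause was not tested. Keeping near-identical libraries separate gave 1235 in Epi, 3766 in PrE, 3177 for the difference and 46211 in the screen.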

Other observations

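The tests of explanations here were chosen after the results were seen; the splits of the samples were planned. In the screen, gastrulation genes were higher in the Bend3 knockout of batch 8 (5 of 5 up, median log2 change 2.38) and lower in the libraries labelled as knockouts of Elf5 (-1.88), Zbtb17 (-1.86) and Suz12 (-1.59). Germline genes were higher in the knockouts of Nelfb, with 7 of 17 up (median 1.21), and Gtf2b, with 6 of 19 up (0.99), and lower in that of Otx2 (-1.06), where Nodal targets were lower as well (-1.13, 3 of 7 down). P53 targets were lower in the Mcrs1 knockout, 8 of 20 (median -0.77). Autophagy genes were higher in 10 knockouts (3 with an estimated correlation). In the Atrx knockout imprinted genes tested lower (adjusted p = 6.82e-04), against a median of 0.09 and a mean of -0.21.

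In the GSK-J4 libraries at E5.0 the rise of primitive endoderm markers went with the wider PrE transcriptome. Of 168 genes enriched in control PrE libraries of another table, 149 were measured, 112 rose and 1 fell (median log2 change 2.57), and 82.6% had each treated library above each control, where chance gives 5%. Of the enriched genes 16 belong to the primitive endoderm list. Of 259 genes enriched in control Epi libraries 117 fell and 11 rose (median -0.842, against -0.307 from dilution by such cells alone). This is consistent with primitive endoderm cells among the collected cells. Against dilution by them as the only change, Pou5f1, at 0.144 to 4.99 TPM in control PrE libraries, was higher in each treated library, at 98.8 to 126 TPM against 55.3 to 68.2. A change of scale was argued against, since the list's median stayed at 4.07 with quantile normalization. A single share of cells like control PrE was argued against, since enriched genes reached unequal parts of their PrE level (quartiles 6.01% and 60%). Of the 50 most abundant, 56% gained at least 50% of what that share would bring. Insig1 went from 166 to 127 TPM against 4564 in PrE and Srgn from 16.6 to 1088 against 1954. A change of epiblast cells toward endoderm was not tested.

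In the batch 8 Bend3 comparison the highest Y-linked value in a knockout library was 0.0313 TPM, so the groups may come from embryos of different sex. Genes on X and Y were 4.51% of the changed genes with a position (127 of 2818) and 3.7% of the tested genes. Without them the count was 2754, so most calls lay elsewhere. With so few tested genes on X and Y this could hardly have come out otherwise. Effects of sex on genes of other chromosomes were not tested. No biological explanation was tested.

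Extra-embryonic markers differed between control groups of the batches, with a median ratio of variance between to within groups of 37.3 (all genes 8.06). Within batches, at 22.5 (2.44), groups may likewise differ by more than the knockout. Plac1 ranged over control groups from 0.297 to 624 TPM and Krt8 from 96.4 to 1080 TPM. Both lowest values are from batch 8, whose stage is uncertain, and were 10 and 530 TPM without it. The 37.3 includes it. Within batches Y-linked transcripts had a ratio of 13.9 (permutation p = 1e-05, the smallest that 100000 resamples can give; 7.81 without batch 8), consistent with libraries of a group sharing embryos. Replicates may then not sample embryos independently.

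Splits of 3 against 3 libraries give 10 and are too few for a share under 0.05; the real split alone, 1 of 10, gave as many calls in each of 6 comparisons. The real and the highest other counts were 115 and 0 for GSK-J4 at E4.5, 3023 and 0 at E5.0, 1027 and 0 in Epi, 6 and 0 for the Zbtb17 knockout at E4.5 and 1246 and 0 for dTAG. For the Zbtb17 knockout at E5.0 they were 2978 and 1699. That other split set controls 1 and 3 with knockout 3 against the rest, and its cause was not tested. Simulated libraries with no change gave 846 calls in this shared fit, so a spread taken too small for these libraries stays open, and the own batch gave 671. In EB 2 of 100 assignments within days, the real one included, gave as many calls, 8102 against 8440 for an assignment that exchanges genotypes on 1 day. In the screen the real assignment was 1 of 50, with 41540 calls against 5804. These assignments treat the libraries of a group as independent, so they exclude only a chance draw of libraries. They do not separate an effect of the knockouts from differences between pools of embryos or cultures.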
